A study of Xenopus laevis with 3 samples.

How the data were processed

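The series measured RNA of anterior and posterior endoderm of Xenopus laevis embryos at stages 30, 39 and 46 on spotted cDNA arrays. Per the labels, endoderm was dissected by hand, total RNA was extracted with TRIZOL, and cDNA was made from oligo(dT) primers with dye-labelled dUTP. The anterior cDNA carried Cy5 and the posterior cDNA carried Cy3 on every array. There was no array with the dyes exchanged, so in a single ratio the region and the dye cannot be told apart. Each stage had 2 arrays, called A and B here, which makes 6 arrays in 3 deposited samples. The labels do not say whether A and B held separate dissections, so where A and B served as replicates, their spread was taken as that between hybridisations.

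The deposited scanner files gave, for each of 21504 spots and both dyes, the median pixel intensity of the spot and of its local background, with the background SD. These intensity values were linear, neither background-subtracted nor normalised. The deposited files also gave the percent of saturated pixels per spot, and a score from the spot-finding software that marked spots it had not found. Per the labels the scanner gain was set on each slide by the first sign of a saturated signal. The authors' own table held 1 ratio per clone and stage, made by the authors from both arrays of a stage with GeneData Refiner and Expressionist, whose versions are not given in the sources used here. Set against the log2 ratios computed here, the authors' ratio was anterior over posterior at each stage (r across probes 0.995, 0.869 and 0.978 at stages 30, 39 and 46). At stages 39 and 46 it followed the ratio before loess more closely (r 0.942 and 0.984) than the ratio after it. The authors' table was used only as an alternative.

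The ratios were computed from the scanner files in R 4.3.3 with limma 3.58.1, and the files were read with data.table (version 1.17.8). Background was corrected with normexp and an offset of 50. Ratios were normalised within each array by loess with a span of 0.3, to which the 239 control spots and spots not found gave no weight, and these spots were then left out. No scaling was applied between arrays. The log2 ratio is that of anterior over posterior, so a positive value means more signal in anterior endoderm. A spot was well above background where its median exceeded the local background median by over 2 background SDs. A probe was tested when it was so in at least 1 channel on at least 2 of the 6 arrays, which left 15640 probes, and a comparison used those with a value on its arrays.

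All 6 arrays entered 1 limma fit with a mean per stage and 3 residual degrees of freedom, followed by empirical Bayes moderation. It gave the anterior against posterior comparison at each stage and the contrasts between stages, with an F-test over the 3 stages. For the comparison across the stages, the arrays of a stage were averaged first and limma was fitted to the 3 stage means, so that differences between stages counted as error. Stages 46 and 30 were compared within each region by the separate-channel method of limma (lmscFit, intraspot correlation 0.951) after Aquantile normalisation between arrays. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. A ratio with 1 region not well above background is given as at least that fold, from the normalised channels, and no fold is given where neither region was. Such a bound allows for the dim signal and not for the spread between arrays.

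Probe names were the protein annotations in the scanner files, which give the best database match, often of another species, and are cut short. No genome positions came with the probes. Of the spots, 8187 had no annotated match and 5198 had a usable name, with 1895 different names. The rule for naming genes asked for a gene symbol, which the files did not give, so an annotated name was used in its place. Uninformative names and names with words for certain non-vertebrate organisms were left out by a filter that was extended after the ranking had been seen. A non-vertebrate name without such a word could remain. Among named probes past the threshold with the same direction on every array of the comparison, the rule took the 10 largest differences in each direction per stage, and 5 in each direction between stages 46 and 30 and within a region, with the brightest passing probe of a name. At stage 39, 1 gene that the rule took is not reported here. Where no probe passed, it took those over 2-fold the same way on all arrays. The rule, the comparisons, the gene lists and the alternatives were fixed before the data were examined.

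The 31 gene lists covered endodermal organs, other tissues that a dissection could carry, and pathways, and 568 spots matched 201 of their symbols. A list gene had the value of its brightest probe with a value on all 6 arrays, whether past the threshold or not, so it can differ from the probe that the naming rule took. The 15 lists with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01, against 10132 genes or unnamed probes, and again with an estimated correlation. The lists to describe, and up to 4 members of each with the largest change, were picked after the results were seen.

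The method was tested on simulated data with known changes of 1.5-fold, 2-fold and 4-fold in 67, 67 and 66 probes. At 2-fold it recovered 97.0%, 92.5% and 97.0% of them at stages 30, 39 and 46, and 89.6% between stages 46 and 30, while at most 10 unchanged probes were called. The simulated probes carried no dye bias of their own, so these false calls do not cover a ratio set by the dye. The fit to 3 stage means recovered 7.46% at 2-fold and 65.2% at 4-fold when the ratios varied between stages as in the data, and 100% of both when they did not. Within anterior endoderm 8.96% were recovered at 2-fold and 50% at 4-fold, so small changes were seldom detectable there. In that comparison 13 of 11590 unchanged probes were called. With few changed probes recovered, these false calls were a larger share of all calls than at a single stage. The comparison within posterior endoderm was not simulated. A muscle list of 14 members shifted by -0.5 at stage 39 was recovered in 7 of 10 simulations and by -1 in 10 of 10, with 6 and 1 of 590 other list tests called. The simulated genes varied independently, while the correlation estimated in the data ran from -0.182 to 0.523 over the tested lists. These counts therefore do not show how often camera calls a list of correlated genes falsely.

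The alternatives were other background corrections, print-tip loess, median centring, scaling between arrays, other filters on dim probes, spots not found kept, the array letter as a block, a size rule with no test, the authors' values, other between-array normalisations for the comparisons within a region, an estimated correlation and the mean over probes for the lists, and each array left out in turn. With an array left out, the lone array of its stage was assumed to vary as the others did. The array letters did not pair the arrays, since A minus B differences were unrelated between stages (r across probes -0.0952, -0.0436 and 0.0362).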

Results

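Endoderm of Xenopus laevis embryos was compared between its anterior region, which later forms the lung, stomach, pancreas and liver among other organs, and its posterior region, which forms the intestine. The series set out to find genes related to these organs. RNA of both regions was hybridised together to 2 cDNA arrays at each of stages 30, 39 and 46, with anterior cDNA in Cy5 and posterior cDNA in Cy3. Median spot intensity was 2988.5 (anterior) and 3037 (posterior) on stage 30 array A, and 1480 and 1954 on stage 30 array B. It was 949 and 1135 on stage 39 array A, 805 and 975 on stage 39 array B, 607 and 807 on stage 46 array A, and 667 and 874 on stage 46 array B. The share of spots well above background ran from 39.7% (anterior, stage 30 array B) to 63.2% (posterior, stage 30 array A). Log2 ratios of arrays A and B of a stage correlated across probes with r of 0.848, 0.947 and 0.935 at stages 30, 39 and 46, while arrays of different stages correlated with r between 0.0444 and 0.337. Probes are not independent replicates, and the number of arrays limits the precision of every value.

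At stage 30, before the organs had formed, serotransferrin, apolipoprotein E, an Na+/K+-exchanging ATPase and glutamine synthetase were higher in anterior endoderm, and glucose-6-phosphatase, the posterior protein and tubulin alpha-2 were lower. Serotransferrin, the iron carrier of blood plasma, was 5.10-fold higher in anterior endoderm (clone XL105j13, log2 ratio 2.35 ± 0.06, SE, n = 2 arrays, adjusted p = 6.79e-07), and all 3 of its probes passed in that direction. Also higher were apolipoprotein E, which carries lipids in plasma (1.54 ± 0.05, adjusted p = 3.82e-06, 4 of 4 probes), an Na+/K+-exchanging ATPase, which pumps sodium out of cells (1.55 ± 0.06, adjusted p = 5.17e-06, 10 of 10 probes), and glutamine synthetase, which fixes ammonia (1.34 ± 0.09, adjusted p = 3.96e-05, 6 of 6 probes). Glucose-6-phosphatase, which releases free glucose, was lower in anterior endoderm (-1.52 ± 0.09, adjusted p = 2.93e-05, 5 of 5 probes), as were the probe annotated as posterior protein (-1.34 ± 0.10, adjusted p = 4.53e-05, 4 of 5 probes) and tubulin alpha-2, a subunit of microtubules (-1.34 ± 0.06, adjusted p = 1.49e-05, 6 of 6 probes). The other named genes higher in anterior endoderm included a sodium-dependent multivitamin transporter (1.91 ± 0.10), nucleoside diphosphate kinase (1.59 ± 0.08) and ficolin 1 (1.07 ± 0.10). They also included a cortical cytoskeleton-associated protein (at least 2.48-fold), phosphoenolpyruvate carboxykinase (1.12 ± 0.07) and a probe whose annotation is shortened after pyruvate dehydrogenase inside an open bracket, which leaves open whether the enzyme or a regulator of it is meant. The signal of this probe was not well above background in either region, and 1 of 4 probes of this annotation passed. The other named genes lower in anterior endoderm included an AHNAK-related protein (-1.30 ± 0.05), the hatching enzyme UVS.2 (-1.12 ± 0.06) and DB83 (at least 2.18-fold lower, 1 of 3 probes). They also included annexin II type 1 (-1.11 ± 0.07), periplakin of desmosomes (-1.07 ± 0.06, 1 of 2 probes), tektin of cilia (-1.06 ± 0.08) and an epidermal keratin of 47 K (-1.06 ± 0.09). For phosphoenolpyruvate carboxykinase and for UVS.2, 1 of 3 probes passed in the direction named here and 2 passed in the opposite one.

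Among organ genes at stage 30, 5 of 6 measured genes of liver metabolism were lower in anterior endoderm and 1 was higher, and the counts adjusted over the list alone were the same. These were led by g6pc (-1.52), fbp1 of glucose synthesis (at least 1.95-fold lower), sds (-0.50) and hal (-0.38), enzymes that break down serine and histidine. Of 12 measured genes of liver secreted proteins, 4 were higher, 4 were lower and 4 did not pass, with 4 and 4 also adjusted over the list alone. They included tf at 2.35, the complement genes c9 at -0.90 and cfb at 0.59, and plasminogen, plg, at -0.47. Of 8 hindgut and posterior patterning genes, 1 was higher, 3 were lower and 4 did not pass, with 1 and 3 adjusted over the list alone. Here cdx2, a regulator of intestinal identity, had -0.37 (adjusted p = 0.00444) and hoxa7, a posterior hox gene, had -0.43 (adjusted p = 0.0044, and 0.0727 with no background subtraction). Of 7 intestine genes, 2 were higher, 3 were lower and 2 did not pass, with 2 and 3 adjusted over the list alone. Villin, vil1, of the brush border had -0.47, and the phosphatase gene alpl had 0.49. Lists with under 5 measured genes were not tested. Of 4 early endoderm genes, 2 were higher, 1 was lower and 1 did not pass, also adjusted over the list alone. Here cer1, a secreted antagonist of Nodal, BMP and Wnt signals, had -0.86 ± 0.08 (adjusted p = 0.000135) and endodermin 0.57 ± 0.06 (adjusted p = 0.00022). Of 3 exocrine pancreas genes, 2 were higher and 1 was lower, also adjusted over the list alone, with 1 higher without stage 30 array A. The 1 measured gene of stomach and oesophagus, sox2, was lower, also adjusted over the list alone (-0.61 ± 0.08, adjusted p = 0.000556), although 2 of its 4 probes passed as higher. None of the 15 lists passed camera at this stage, where 1 had an unadjusted p under 0.05, and adjusted p was 0.116 for liver metabolism, 0.984 for liver secreted proteins, 0.806 for hindgut and 0.837 for intestine. Without stage 30 array A the hindgut counts were 2 higher and 4 lower, 2 liver secreted protein genes were lower and no liver metabolism gene was higher, while without stage 30 array B 1 early endoderm gene was higher. For liver secreted proteins the median was -0.04, the mean 0.12 and the direction of the test down.

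In the limma fit, 7730 of 13725 probes differed between the regions at stage 30, 3939 of them higher and 3791 lower in anterior endoderm. Of these, 78 were over 2-fold higher and 94 over 2-fold lower. The count over 2-fold, 172, was 112 with no background subtraction and 277 with plain subtraction. Since anterior cDNA always carried Cy5, region and dye cannot be told apart in these counts or in those of the other stages. Their error was the spread between hybridisations.

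At stage 39, the hatching enzyme UVS.2, glucose-6-phosphatase and complement C3 were lower in anterior endoderm, and most differences over 2-fold had that direction. UVS.2 was at least 10.6-fold lower in anterior endoderm (log2 ratio -3.40 ± 0.05, SE, n = 2 arrays, adjusted p = 7.7e-08, 3 of 3 probes). Glucose-6-phosphatase (-2.38 ± 0.09, adjusted p = 1.35e-06, 4 of 5 probes) and complement C3 (-1.99 ± 0.06, adjusted p = 4.69e-07, 7 of 7 probes) were lower as well. The probe with the largest positive ratio among the named genes matched a human AML1-EVI-1 fusion gene (2.60 ± 0.07, adjusted p = 4.14e-07). SOX-2, a transcription factor of the foregut and the nervous system, was higher by 1.85 ± 0.18 (adjusted p = 7.42e-05, 4 of 5 probes), although its brightest probe had 0.01. Further named genes higher in anterior endoderm were the probe with the shortened pyruvate dehydrogenase annotation (2.63-fold, 2 of 6 probes), complexin 2 of synaptic vesicle release (1.28 ± 0.06), the nuclear receptor COUP-TF2 (1.14 ± 0.09), inter-alpha-trypsin inhibitor heavy chain, a plasma protein (2.14-fold), and succinyl-CoA:3-ketoacid-CoA transferase, which opens the use of ketone bodies (1.06 ± 0.08). Annexin I (1.04 ± 0.06, 2 of 3 probes) was higher as well, as was the kinase SRPK1 (0.99 ± 0.06). Peripherin also passed in that direction, with a signal not well above background in either region and 1 of its 3 probes past the threshold the opposite way. Further genes lower in anterior endoderm were guanidinoacetate N-methyltransferase, which makes creatine (-2.24 ± 0.10), phosphoenolpyruvate carboxykinase (-1.95 ± 0.07, with 1 of 3 probes past the threshold the opposite way), and adrenodoxin (-1.90 ± 0.07). Annexin II type 1 (-1.89 ± 0.07) was lower too, with tubulin alpha-2 (-1.85 ± 0.06) and carbonic anhydrase XIV (at least 3.42-fold lower). The carboxykinase probe named here (XL097a01) was not the one named at stage 30 (XL097b01), and neither changed direction between stages. The means at stages 30, 39 and 46 were -0.67, -1.95 and -0.24 for XL097a01, and 1.12, 0.89 and 0.30 for XL097b01.

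Of 6 measured genes of liver metabolism at stage 39, 5 were lower in anterior endoderm and 1 was higher, also adjusted over the list alone, and the list passed camera (median -1.42, adjusted p = 0.0152; adjusted p = 0.334 with an estimated correlation). Beside g6pc, fbp1 had -1.64 (adjusted p = 3.79e-06) and hal had -1.20 (adjusted p = 8.35e-06). Among the tested lists of other tissues, epidermis and skeletal muscle passed camera in the same direction at this stage. Notochord and cartilage had 2 genes higher and 2 lower (camera adjusted p = 0.882), and fibroblast and collagen had 2 higher and 4 lower (camera adjusted p = 0.556). The epidermis list includes a keratin of simple epithelia, so it does not mark epidermis alone. Of 7 epidermis and ectoderm genes, 5 were lower and 2 did not pass, with 5 adjusted over the list alone (median -0.81, adjusted p = 0.0362; adjusted p = 0.334 with an estimated correlation), among them the larval keratin xk81a1 (-1.38) and krt18 of simple epithelia (-0.81). Of 14 skeletal muscle genes, 9 were lower, 3 were higher and 2 did not pass, with 9 and 3 adjusted over the list alone (median -0.46, adjusted p = 0.0400; adjusted p = 0.334 with an estimated correlation). The fast myosin light chain mylpf had -1.71, the fast troponin tnni2 -1.44, the muscle determination gene myf5 -1.40 and desmin, des, -0.98. Of 8 hindgut and posterior patterning genes, 5 were lower, 1 was higher and 2 did not pass, with 5 and 1 adjusted over the list alone, and the list did not pass camera (median -0.87, adjusted p = 0.0704). Its posterior hox genes hoxa10 (-1.51 ± 0.07, adjusted p = 3.18e-06), hoxb9 (at least 2.21-fold lower) and hoxa11 (-0.88 ± 0.07) were lower together with cdx2 (2.01-fold, adjusted p = 2.09e-05). Of 12 liver secreted protein genes, 4 were higher, 5 were lower and 3 did not pass, with 4 and 5 adjusted over the list alone (adjusted p = 0.386), and the lower ones included f13b of clotting (-1.43), c9 (-1.17) and apoc1 (-1.15). Of 5 genes of proteases and lysosome, 4 were lower and 1 did not pass, with 4 adjusted over the list alone (adjusted p = 0.0917), led by grn (-1.02), cd63 (-0.59) and ctsa (-0.42). Of 4 early endoderm genes, 2 were lower, 1 was higher and 1 did not pass, also adjusted over the list alone. Endodermin had -1.55 ± 0.06 (adjusted p = 1.14e-06, 2 of 2 probes), vegt, a maternal regulator of endoderm, had -1.11 ± 0.07 (adjusted p = 6.8e-06, 2 of 2 probes), and gata6 was at least 1.62-fold higher. Of 3 exocrine pancreas genes, 1 was higher and 2 were lower, also adjusted over the list alone, with none higher without stage 39 array A. The hormone gene sst, the 1 measured gene of endocrine pancreas, was higher both over all probes and adjusted over the list alone (0.67 ± 0.08, adjusted p = 0.000198). Without stage 39 array A, 2 liver secreted protein genes were higher. Without stage 39 array A, and likewise without B, 1 skeletal muscle gene and no liver metabolism gene were higher. The muscle call ended without stage 30 array A (adjusted p = 0.0559) and with median centring (adjusted p = 0.117), and the epidermis call ended with median centring (adjusted p = 0.117) and with the mean over a gene's probes (adjusted p = 0.112).

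In the limma fit, 8593 of 13520 probes differed between the regions at stage 39, 4297 higher and 4296 lower in anterior endoderm. Among the larger differences the directions were unequal, with 67 probes over 2-fold higher and 568 over 2-fold lower. With median centring in place of loess these counts were 130 and 508.

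**Figure D1:**
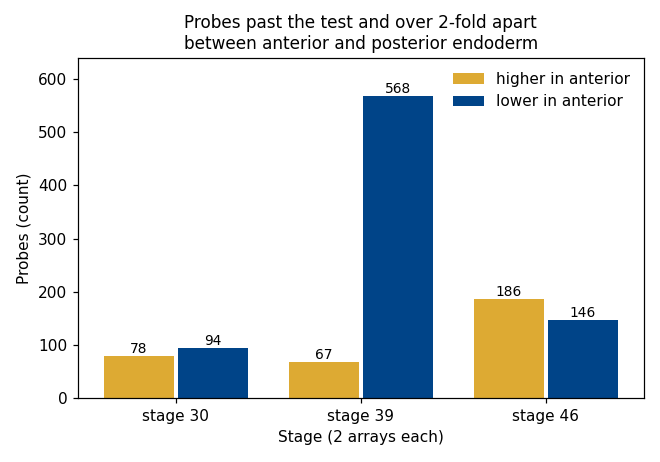
Number of probes (y axis, count) past the threshold of the limma test and over 2-fold higher (yellow bars) or lower (blue bars) in anterior than in posterior endoderm at each stage (x axis, 2 arrays per stage). At stage 39 the counts were 67 higher and 568 lower, against 78 and 94 at stage 30 and 186 and 146 at stage 46.

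At stage 46, when the organs were distinct, inter-alpha-trypsin inhibitor heavy chain, glutamine synthetase and pyruvate carboxylase were higher in anterior endoderm, and apolipoproteins C-I and E were lower. Inter-alpha-trypsin inhibitor heavy chain was 6.23-fold higher in anterior endoderm (clone XL105a08, log2 ratio 2.64 ± 0.06, SE, n = 2 arrays, adjusted p = 2.14e-07, 2 of 2 probes). Glutamine synthetase (2.44 ± 0.09, adjusted p = 9.44e-07, 6 of 6 probes), pyruvate carboxylase, an enzyme of glucose synthesis (2.09 ± 0.06, adjusted p = 3.22e-07, 3 of 3 probes), and coagulation factor XIII B (2.01 ± 0.07, adjusted p = 9.44e-07, 2 of 2 probes) were higher too. Apolipoprotein C-I (-2.16 ± 0.06, adjusted p = 2.51e-07) and apolipoprotein E (-1.69 ± 0.05, adjusted p = 4.48e-07, 3 of 3 probes) were lower in anterior endoderm. The other named genes higher there were glutathione transferase omega 1 of detoxification (2.40 ± 0.14), the lectin galectin-3 (2.33 ± 0.07) and succinyl-CoA:3-ketoacid-CoA transferase (2.20 ± 0.08), then a carbonate dehydratase (2.13 ± 0.11), methionine adenosyltransferase (at least 3.59-fold, 1 of 2 probes) and pctp-L (1.73 ± 0.08). The other named genes lower there included an erythrocyte membrane protein (-1.80 ± 0.07), glycerol-3-phosphate dehydrogenase (-1.78 ± 0.05, with 2 of 3 probes past the threshold the opposite way) and annexin II type 2 (-1.59 ± 0.13). They also included channel-activating protease 1 of epithelial sodium transport (-1.53 ± 0.06), carbonic anhydrase VII (-1.51 ± 0.10), tubulin alpha-2 (at least 2.79-fold lower) and hydroxyacid oxidase 2 (-1.46 ± 0.06). A vitamin D3 hydroxylase-associated protein passed as lower with a signal not well above background in either region.

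Of 7 measured genes of oxidative phosphorylation at stage 46, 6 were higher in anterior endoderm and 1 did not pass, with 6 adjusted over the list alone (median 0.41, adjusted p = 0.0387; adjusted p = 0.603 with an estimated correlation). They were the ATP synthase genes atp5f1c (0.60 ± 0.06) and atp5f1b (0.48 ± 0.06) and the complex I genes ndufa10 (0.50 ± 0.07) and ndufa9 (0.41 ± 0.06), among others. This was the one list that passed camera at stage 46. Its call ended without stage 30 array A (adjusted p = 0.0812), without stage 39 array A (adjusted p = 0.0916) or without stage 46 array B (adjusted p = 0.0853), and without stage 46 array A 3 lists passed. Of 5 heat shock and stress genes, 4 were higher and 1 did not pass, also adjusted over the list alone (adjusted p = 0.0762), with the chaperone of the endoplasmic reticulum hsp90b1 at 1.41 ± 0.05 (adjusted p = 9.85e-07) and xbp1, a regulator of secretory cells, at 0.64. Of 12 liver secreted protein genes, 5 were higher, 4 were lower and 3 did not pass, with 6 and 4 adjusted over the list alone (adjusted p = 0.683), and cfb had 1.36 beside those named above. Of 6 liver metabolism genes, 2 were higher, 3 were lower and 1 did not pass, also adjusted over the list alone (adjusted p = 0.441), with g6pc at -0.77. Of 8 hindgut and posterior patterning genes, 2 were higher, 3 were lower and 3 did not pass, with 2 and 3 adjusted over the list alone (adjusted p = 0.441), and cdx2 (-1.12 ± 0.08, adjusted p = 1.59e-05, 2 of 2 probes) and hoxa10 (-0.64 ± 0.07) were lower. Of 14 skeletal muscle genes, 3 were higher, 7 were lower and 4 did not pass, with 3 and 8 adjusted over the list alone (adjusted p = 0.196), and mylpf, lower at stage 39, had 1.41 while the tropomyosin gene tpm1 had -1.09. Of 7 epidermis and ectoderm genes, 3 were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.752), with the epithelial keratins krt8 at -1.24 and krt18 at 0.84. Without stage 46 array A, and likewise without B, no hindgut gene was higher and 2 were lower. The epidermis counts were 2 and 1 without A and 2 and 2 without B, and those of liver secreted proteins 4 and 2 without B. Of 3 exocrine pancreas genes none passed, over all probes or adjusted over the list alone. The 1 measured gene of stomach and oesophagus, sox2, was at least 1.71-fold higher (adjusted p = 0.000146, 4 of 4 probes), and that of endocrine pancreas, sst, was higher by 0.70 ± 0.08 (adjusted p = 0.000213), both also adjusted over the list alone. At stage 30 the brightest sox2 probe was lower while 2 of 4 probes passed as higher, so not all its probes changed direction. The sox2 probe named at stage 39 had means of 0.24, 1.85 and 1.59 at stages 30, 39 and 46.

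In the limma fit, 7715 of 13651 probes differed between the regions at stage 46, 4199 higher and 3516 lower in anterior endoderm, with 186 over 2-fold higher and 146 over 2-fold lower. Without stage 46 array A the count was 4512, and without stage 46 array B it was 4456.

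**Figure D2:**
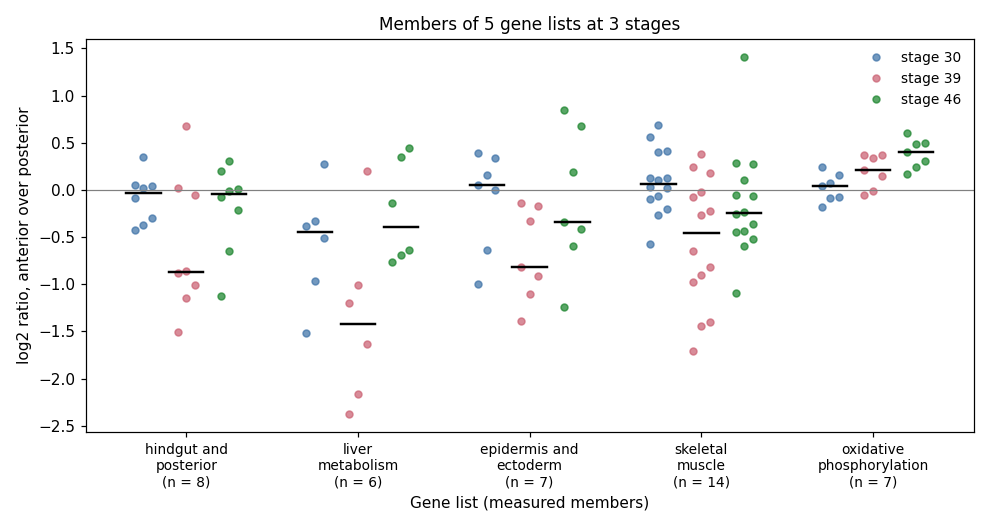
Log2 ratio of anterior over posterior endoderm (y axis) for each measured member (points) of 5 gene lists (x axis, with the number of members n) at stages 30, 39 and 46 (colours), with black lines at the medians. The medians of liver metabolism (-1.42), epidermis (-0.81), skeletal muscle (-0.46) and hindgut (-0.87) lay lowest at stage 39, and that of oxidative phosphorylation was 0.41 at stage 46.

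The ratio at stage 46 was then set against that at stage 30, to ask whether the difference between the regions changed while the organs formed. A dye effect of a probe that is the same on all arrays cancels in this comparison. Apolipoprotein E turned from higher to lower in anterior endoderm, with stage means of 1.54, -1.24 and -1.69 and a difference of -3.24 ± 0.08 (SE, n = 2 arrays per stage, adjusted p = 2.73e-07, 3 of 3 probes). The Na+/K+-exchanging ATPase went from 1.55 over 0.03 to -1.04 (difference -2.58 ± 0.08, adjusted p = 9.07e-07, 10 of 10 probes). In the other direction, galectin-3 went from -0.29 over 0.02 to 2.33 (difference 2.62 ± 0.10, adjusted p = 1.66e-06, 2 of 2 probes) and pyruvate carboxylase from -0.36 over 0.04 to 2.09 (difference 2.46 ± 0.08, adjusted p = 1.17e-06, 2 of 3 probes). Glutathione transferase omega 1 (2.86 ± 0.20), succinyl-CoA:3-ketoacid-CoA transferase (2.71 ± 0.11) and inter-alpha-trypsin inhibitor heavy chain (2.35 ± 0.09) also rose toward anterior endoderm. Nucleoside diphosphate kinase (-2.64 ± 0.12), apolipoprotein C-I (-2.39 ± 0.08) and the multivitamin transporter (-2.21 ± 0.14) fell. Where a name had its brightest probe over 2-fold apart between the stages and another probe, the second probe passed in the same direction for 32 of 42 names, passed in the opposite direction for 5 and did not pass for 5.

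**Figure D3:**
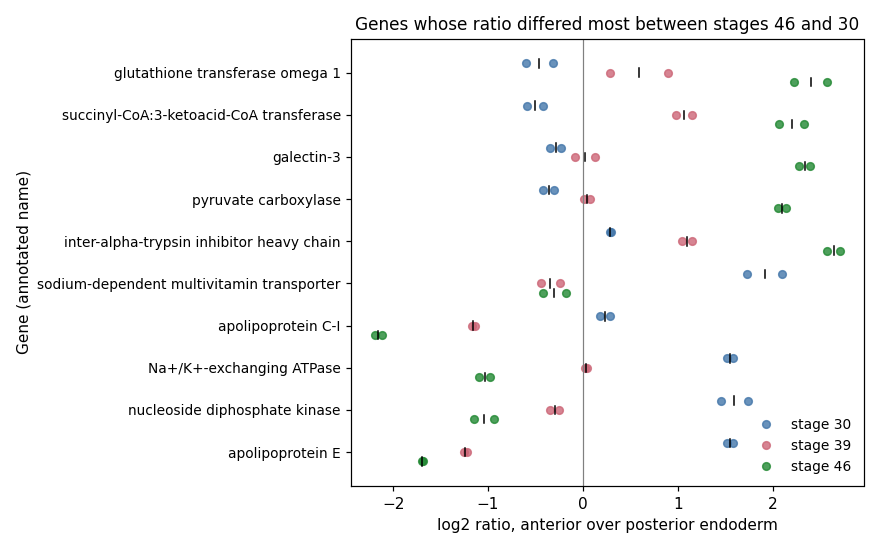
Log2 ratio of anterior over posterior endoderm (x axis) on each array (points, 2 per stage, colours for stages 30, 39 and 46) for the 10 genes with the largest differences between stages 46 and 30 (y axis, annotated names), with black ticks at the stage means. Apolipoprotein E moved from 1.54 at stage 30 to -1.69 at stage 46, and galectin-3 from -0.29 to 2.33.

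Of 12 liver secreted protein genes, 5 rose toward anterior endoderm between stages 30 and 46, 4 fell and 3 did not pass, with 5 and 4 adjusted over the list alone (adjusted p = 0.890). Beside apoc1 and the inter-alpha-trypsin inhibitor, f13b rose by 2.31 ± 0.11 and tf had -1.51 ± 0.09. Their median was -0.05 and their mean 0.19, with the direction of the test up. Of 7 oxidative phosphorylation genes, 5 rose and 2 did not pass, with 5 adjusted over the list alone (adjusted p = 0.140), including atp5f1b (0.56 ± 0.09) and atp5f1c (0.53 ± 0.08), while 3 rose without stage 46 array B. Of 14 skeletal muscle genes, 8 fell, 2 rose and 4 did not pass, with 8 and 2 adjusted over the list alone (adjusted p = 0.140), led by mylpf (1.47 ± 0.17), tpm1 (-0.90 ± 0.13), actc1 (0.86 ± 0.08) and myod1 (-0.79 ± 0.11). No list passed camera for this difference, where 2 of 15 had an unadjusted p under 0.05. Between stages 30 and 39, 5 of 6 liver metabolism genes fell and 1 rose (median -0.84), and between stages 39 and 46, 5 rose and none fell (median 1.24).

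In the limma fit the ratio differed between stages 46 and 30 for 6878 of 12715 probes, 3694 higher and 3184 lower at stage 46. Of these, 353 were over 2-fold higher and 268 over 2-fold lower. Between stages 39 and 30 the ratio differed for 7645 of 12629 probes, between stages 46 and 39 for 6373 of 12531, and the F-test over the 3 stages passed for 9018 of 11790.

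Across the 3 stages taken as replicates, tubulin alpha-2 was the one named gene over 2-fold in the same direction on all 6 arrays, with stage means of -1.34, -1.85 and -1.48. Its mean of -1.56 ± 0.16 (SE, n = 3 stages) did not pass limma (adjusted p = 0.366), whereas with each array counted as an observation it did (adjusted p = 3.96e-08). No array had the dyes exchanged, and no probe of another alpha tubulin had a value. Annexin II type 1, with stage means of -1.11, -1.89 and -1.20, came just short of 2-fold on stage 30 array B alone (-0.993). In all, 0 of 11790 probes passed, with 1165 at an unadjusted p under 0.05. In simulations with ratios that varied between stages as in the data, this fit recovered 7.46% of 2-fold and 65.2% of 4-fold differences. Where all ratios were alike at the 3 stages it recovered 100% of both. A miss therefore does not show that the regions were alike. Steady ratios among unsteady ones were not scored apart, so a miss does not show that a ratio was unsteady either. With each array as an observation 7857 passed, 77 of them over 2-fold, a test that does not count differences between stages as error. Stage means correlated across probes with r of 0.102 between stages 30 and 39, 0.0866 between stages 30 and 46 and 0.338 between stages 39 and 46 (Spearman's rho 0.0446, 0.0997 and 0.349). Of the probes past the threshold at both stages, 2421 of 4634 had the same direction at stages 30 and 39, 2433 of 4128 at stages 30 and 46, and 3476 of 4816 at stages 39 and 46. Of probes over 2-fold at both stages 30 and 39, 37 had the same direction and 6 opposite ones, where chance overlap gives 3.62 and 3.39. At stages 30 and 46 these were 11 and 7 (chance 1.69 and 1.70), and at stages 39 and 46 they were 56 and 7 (chance 6.01 and 7.14).

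Stages 46 and 30 were also compared within each region, in 1 dye. In the simulation of this comparison in anterior endoderm, false calls were a larger share of the calls than at a single stage, so its calls are less certain. In anterior endoderm, inter-alpha-trypsin inhibitor heavy chain rose by 3.13 ± 0.27 (log2, SE, n = 2 arrays per stage, adjusted p = 7.82e-05). The regulatory subunit of glutamate-cysteine ligase, of glutathione synthesis, rose at least 11.4-fold (adjusted p = 0.000153), and XA6-1 at least 27.1-fold (adjusted p = 0.000631). The heart fatty acid-binding protein rose at least 6.87-fold (adjusted p = 0.0245, 1 of 2 probes) and glutathione transferase omega 1 by 2.74 ± 0.55 (adjusted p = 0.00873). The 47 K epidermal keratin fell by 5.19 ± 0.52 (adjusted p = 0.000234), a bone morphogenetic protein receptor fell at least 30.8-fold (adjusted p = 0.000234), and XLS13A (-3.75 ± 0.30, 2 of 5 probes), the multivitamin transporter (-3.65 ± 0.39) and a scavenger receptor (-3.41 ± 0.37) fell too. Of 12 liver secreted protein genes, 4 rose and none fell, while 2 rose without stage 46 array A or without B, and 1 fell without stage 30 array A or without B. Of 7 oxidative phosphorylation genes, 3 rose and none fell, but none passed without stage 46 array A or without B, and 5 rose without stage 30 array A. Of 8 hindgut genes none passed. Without stage 46 array A the call ended for the fatty acid-binding protein (adjusted p = 0.176) and glutathione transferase omega 1 (adjusted p = 0.0538), as it did without stage 46 array B (adjusted p = 0.117 and 0.0782). For the fatty acid-binding protein it ended also without stage 39 array A (adjusted p = 0.0653) or B (adjusted p = 0.0660). In all, 1692 of 11790 probes changed, 974 rising and 718 falling, 1423 of them by over 2-fold, and the count was 442 without stage 46 array A and 410 without stage 46 array B. For the bone morphogenetic protein receptor, whose fold is given above only as a bound, the estimated log2 change was -4.94 with all arrays. It was -6.06 without stage 46 array A and -3.89 without B, so without B the estimated fall was smaller than that bound.

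In posterior endoderm, serotransferrin rose by 3.31 ± 0.24 (log2, SE, n = 2 arrays per stage, adjusted p = 4.85e-05, 1 of 2 probes) and apolipoprotein E by 3.29 ± 0.31 (adjusted p = 9.86e-05, 2 of 3 probes). Desmin of muscle rose by 3.22 ± 0.28 (adjusted p = 6.94e-05, 1 of 3 probes), the regulatory subunit of glutamate-cysteine ligase at least 9.53-fold and XA6-1 at least 10.4-fold. The 47 K epidermal keratin fell by 5.77 ± 0.52 (adjusted p = 7.63e-05), as did an H,K-ATPase matched to that of the giant toad (-4.26 ± 0.34, adjusted p = 4.85e-05, 5 of 5 probes), galectin-3 (-3.72 ± 0.32, adjusted p = 6.36e-05, 2 of 2 probes), the bone morphogenetic protein receptor (at least 32.3-fold) and Ci-META1, which fell to a level not well above background. Of 8 hindgut genes, cdx2 rose, by 1.84 ± 0.35 (adjusted p = 0.00644, and 0.0584 without stage 46 array B), and none fell, while 1 fell without stage 30 array A. Of 12 liver secreted protein genes, 2 rose and 1 fell, with 3 and 2 without stage 30 array B. The 1 that fell, f13b, ended its call without any other single array (adjusted p from 0.0677 to 0.252). Of 7 oxidative phosphorylation genes, 2 rose and none fell, but none passed without any 1 array of stages 39 and 46, while 1 rose without stage 30 array B and 4 without stage 30 array A. In all, 1433 of 11790 probes changed, 742 rising and 691 falling, 1251 of them by over 2-fold, and the count was 562 without stage 46 array A and 447 without stage 46 array B. For the receptor the estimated log2 change was -5.01 with all arrays, -6.04 without stage 46 array A and -4.05 without B, which is a smaller fall than the bound. For XA6-1 it was 4.02 without A, and for Ci-META1 it was -3.07 without stage 30 array B. These genes have no exact fold above, so the values show only how far the estimates moved. Stage and array pair cannot be told apart within a region, and whether the changes of the regions differ is given by the difference of their ratios between the stages.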

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

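The tests of a constant dye bias on the difference between stages 46 and 30 and on the stage 39 asymmetry, of carried muscle, and of a dye bias of the usual size on tubulin alpha-2 were chosen only after the result was seen.

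The difference between the regions itself differed between stages, by a test of that difference. It passed for 6878 probes between stages 46 and 30, and 9018 probes passed the F-test over the 3 stages. The named genes with the largest positive differences were glutathione transferase omega 1 of detoxification (2.86), the ketone body enzyme succinyl-CoA:3-ketoacid-CoA transferase (2.71), the lectin galectin-3 (2.62), pyruvate carboxylase of glucose synthesis (2.46) and the plasma protein inter-alpha-trypsin inhibitor heavy chain (2.35). Those with the largest negative differences were apolipoprotein E (-3.24), nucleoside diphosphate kinase (-2.64), the Na+/K+-exchanging ATPase (-2.58), apolipoprotein C-I (-2.39) and the sodium-dependent multivitamin transporter (-2.21).

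Of the 4128 probes past the threshold at both stages 30 and 46, 1695 (41.1%) had opposite directions and 2433 the same one. Calls were split almost evenly between the directions, with 51.0% higher at stage 30 and 54.4% at stage 46. Ratios unrelated between the stages would thus give about as many opposite as same directions, so 1695 is not an excess of reversals. A dye bias of a probe that is the same on every array cancels by design in the difference between stages, so it cannot give the difference that 54.1% of all 12715 tested probes passed for, but it would shift the direction at each stage and so the count of 1695. Of 15 other probes of the named genes 14 passed in their gene's direction, but 9 of the 15 were of the Na+/K+-exchanging ATPase, and 5 of the 10 genes had no other probe, so a fault of a single probe stays open for those. Saturation of the stage 30 arrays is argued against as well, since 16 of the 1695 probes (0.944%) were saturated there. A change of gene expression along the gut while the organs formed stays open as a hypothesis, and so does a difference between the dissections or hybridisations of the stages, which the design cannot separate from stage.

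At stage 39, 568 probes were over 2-fold lower and 67 over 2-fold higher in anterior endoderm, with liver metabolism, epidermis, hindgut and skeletal muscle genes among the lower ones. A constant dye bias is argued against, since 549 of the lower probes had a median of -0.0649 at stage 30, -1.22 at stage 39 and -0.37 at stage 46. The ratio of lower to higher counts was 10.7 with no background subtraction, 8 with print-tip loess and 3.91 with median centring, so the normalisation may set part of its size, and nothing run here excludes it. Muscle carried with the posterior piece stays open too, because 9 of 14 skeletal muscle genes were lower and 3 (21.4%) were higher (1 without stage 39 array A or without B), while the abundant muscle actins acta1 and actc1 had -0.03 and 0.24. A difference between the regions at this stage, which the design names, remains possible and was not tested apart from these.

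Tubulin alpha-2 was lower in anterior endoderm at every stage, and its 6 probes had a median of -1.32 over the stages, although 1 of them passed as higher at stage 46 (0.18). In units of the SD of 0.175 that the stages shared across probes this was -7.54, but the gene had been named for being over 2-fold on all 6 arrays, so the value restates that choice and leaves a dye bias of the usual size open. A dye bias set by the sequence of alpha tubulin could give the same ratio at every stage and cannot be told apart from a regional difference, since 0 other alpha tubulin probes had a value and no array had the dyes exchanged. Lower expression in anterior endoderm stays open.

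Spots outside the gene probes also gave signal. Lambda phage DNA spots were above background in 74 of 75 cases where the spot was found (98.7%), and spots with no name on the control plate in 194 of 299 (64.9%). The share was 67.3% for gene spots, 93.1% for dilutions of cytochrome c oxidase I, 86.2% for those of EF1alpha, 42.1% for GFP and 59.5% for spots named nr. The sources used here do not say whether lambda RNA was added to the samples or what the unnamed spots held.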

How the results depend on the processing

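No alternative in this part was chosen after the result was seen. Requiring signal above background in both channels on all 6 arrays gave 2138, 2434 and 2140 probes past the threshold at stages 30, 39 and 46 and 2058 between stages 46 and 30, because 3550 probes were then tested. Across the stages, the mean in the 6-array fit passed for 7857 probes in place of 0, because differences between stages were then no error. With arrays over 2-fold the same way and no test, 131, 502 and 275 probes were counted at stages 30, 39 and 46, a rule that reads size alone. With the authors' values over 2-fold, again a rule on size, 196, 1915 and 427 were counted, and 627 between stages 46 and 30. At stage 39, 1853 of those 1915 were lower in anterior endoderm. The authors' log2 values there differed from the log2 ratios computed here by a median of -0.208, and the cause of the count was not tested. Camera called 0 gene lists with an estimated correlation in place of 4, with 1 unadjusted p under 0.05 at stage 39 and 0 elsewhere. The estimate was -0.182 for liver metabolism, -0.0342 for skeletal muscle and 0.00511 for epidermis, all below the preset 0.01. A higher correlation therefore did not end the calls of these lists. For oxidative phosphorylation the estimate was 0.0741, above the preset.

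Over the 6 fits that left out 1 array, the counts ran from 6606 to 7067 at stage 30, from 5751 to 9105 at stage 39, from 4456 (without stage 46 array B) to 8336 at stage 46, and from 4842 to 6931 between stages 46 and 30. Across the stages limma called 0 in each, with 1128 to 1273 at an unadjusted p under 0.05. Within anterior endoderm they ran from 410 to 2252 and within posterior endoderm from 447 to 2127, lowest without stage 46 array B. Gene lists called ran from 2 (without stage 30 array A) to 6 (without stage 46 array A), and median centring also gave 6. A stage left with 1 array has fewer samples, and the cause was not tested otherwise.

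The alternatives gave 3621 values for 241 pairs of a gene's probe and a comparison, so a gene can count in several pairs. Of these values 3362 kept their side of the threshold or moved by less than the spread. Another 73 lost their call under a test, 92 missed the size rule, 11 gained a call, 83 moved and 0 reversed. Direction was checked only where a call was made. All 83 that moved were among the 173 values set against the authors' ratios. With the array letter as a block, 7254, 8234 and 7227 probes passed at the stages and 6505 between stages 46 and 30. The share of spots well above background was lowest on stage 30 array B (39.7% anterior, 44.0% posterior), and median intensity on stage 46 array A (607 and 807).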

Other observations

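No test in this part was chosen only after the result was seen. Where a name had its brightest probe over 2-fold apart between the regions and another probe was measured, the second probe passed in the same direction for 9 of 10 names at stage 30, 46 of 64 at stage 39 and 30 of 34 at stage 46. It passed in the opposite direction for 1, 6 and 3 names. The authors' ratios had medians of 0.975, 0.802 and 0.924 at stages 30, 39 and 46, and gave no value for 8327, 313 and 392 clones.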
